A study of Mus musculus with 6 samples.

How the data were processed

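The deposited table holds raw read counts per Ensembl mouse gene identifier for 6 libraries, 3 from control mice and 3 from mice on cuprizone diet. Per the labels' protocols, corpus callosum was snap-frozen, tagged ribosomes were pulled down with an anti-HA antibody, RNA was purified with a Direct-zol kit and libraries were made with a Kapa RNA kit. Per the submitters' processing notes, bcl2fastq 2.17 and the mouse build mm10 were used. The aligner, the counting program, the annotation release and the strand setting are not given in the sources used here. Without a known strand setting, reads of genes that overlap on opposite strands may have been assigned to either, and reads shared between close paralogs may have been split or dropped, which touches the level of such genes more than that of others.

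Groups came from the treatment and title of each sample, and each column was matched to its sample by title. The groups share no replicate number and the labels give no batch, so no pairing or batch term entered the model. Replicates of a group were compared by a chi-square test of their counts over genes with at least 10 counts in the pair. The chi-square per degree of freedom ran from 24.4 to 30.6 between controls and from 26.6 to 101 between cuprizone libraries, so no pair agreed within sampling noise and each was counted as 1 replicate.

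Gene names, coordinates, exonic lengths and GC contents were taken from the GENCODE mouse release M21 annotation of GRCm38, the assembly also called mm10. Coordinates are 1-based and span the whole gene, introns included. Of 39017 identifiers 37607 matched, and the 1410 without a match held 0.393% to 0.467% of the counts of a library; they stayed in the tests. All counts were 0 for 15581 genes.

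Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with its default minimum count of 10 and minimum total of 15, which left 16569. Library sizes were scaled with TMM factors, which were 0.915 to 0.941 in controls and 1.05 to 1.11 in cuprizone libraries. Dispersion was estimated with estimateDisp (common biological coefficient of variation 0.215), and cuprizone was compared with control by glmQLFit with robust estimation and glmQLFTest, 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of its F statistic. CPM values use TMM-scaled library sizes and are given as mean ± SD. With totals of 18549360 to 22381307 counts, genes at a few CPM carry a counting error that adds to the spread between libraries. A permutation of 3 against 3 samples cannot give a 2-sided p below 0.1, so no permutation test of single genes was made.

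Of 27 gene lists fixed before the data were examined, the 26 with at least 5 tested members were tested with camera on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the lists, and again with an estimated correlation. With the preset correlation 12 lists passed, and 0 of these passed with the estimated one. The rotation test fry gave adjusted p of 0.0079 for cholesterol biosynthesis and for myelin, 0.0225 for fatty acid synthesis and for p53 targets, and 0.0101 for the integrated stress response, while the other 7 of the 12 lists did not pass it, with adjusted p from 0.186 to 0.544. Genes 9630013A20Rik and Lhfpl3 of the lists had no match by name. The genes named in the text follow a rule also fixed before the data were examined. It takes the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups, leaving out predicted genes, Riken clones and pseudogenes. It adds the 3 members of each list with the smallest adjusted p, and a fixed set that includes Rpl22, Olig1, Mbp, Mog, Srebf2, Abca1, Abcg1 and Apoe. Some genes that the rule takes are left out of the text and of the plots, and they stay in every test and list count. Names outside this rule (Ugt8a, Soat1, Ddit4, Anxa2 and Klk6) were chosen after their values were seen. The closing section's own lists were drawn up after the main results had been seen. Its tests of liver X receptor targets and of further striatal and cortical markers were set before their results. The further striatal markers were picked as not past the threshold.

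The procedure was tested on simulated counts for the 16569 genes, drawn once with the means and library sizes of the real samples. In them 50 genes were changed at each of 4 sizes and the immediate early list was raised, far fewer genes than were called in the data. It recovered 84% of genes with a log2 fold change of -2, 28% at -1, 64% at 1 and 88% at 2, and 6.16% of its calls were unchanged genes. Alternatives were RLE and upper-quartile scaling, TMM factors without the myelin list and the 20 most abundant genes, no filter on low counts, a filter of CPM over 1 in at least 3 samples, DESeq2 1.42.0, limma-voom, a fit without robust estimation, counts thinned to the smallest library, each library left out in turn and, for lists, an estimated correlation, fry, and lists without shared members. Removal of trends on GC content and exonic length was added after the data were seen. Intervals of list medians are 95% bootstrap intervals over genes from 10000 draws, and genes are not independent replicates. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.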

Results

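RNA pulled down with tagged ribosomes was sequenced from the corpus callosum, the large white matter tract that joins the hemispheres, of C57BL/6 mice. The mice carry RiboTag and Olig1-Cre, a pair meant to tag ribosomes of the oligodendrocyte lineage. In these mice the ribosomal protein RPL22 bears an HA tag in cells in which Cre has been active, and an antibody against HA pulls down tagged ribosomes with the RNA they carry. Control libraries (replicates 24, 26 and 27) were compared with libraries from mice fed 0.2% cuprizone (replicates 30, 31 and 32), a copper chelator that kills oligodendrocytes and strips myelin. The protocol in the labels describes females aged 8 to 10 weeks, feeding for 6 or 9 weeks and a recovery of 3 weeks on control diet. It does not say which of these applies to the cuprizone libraries. The stage of the lesion is therefore not given in the sources used here. Total counts ran from 18549360 to 18771737 in the control libraries and from 19455245 to 22381307 in the cuprizone libraries. The title of the series names cholesterol homeostasis in oligodendrocytes, and the comparison asks which captured transcripts, those of cholesterol metabolism in particular, differed between the diets.

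Myelin transcripts fell steeply in the cuprizone libraries. Mbp, which encodes myelin basic protein, went from 34363 ± 9088 CPM to 5574 ± 2329 CPM (SD, n = 3 per group), a log2 fold change of -2.62 ± 0.40 (SE). Mog, on the outer face of the myelin sheath, had a log2 fold change of -3.67. Of 20 genes of cholesterol synthesis 15 fell, by a smaller amount, and of 24 genes of the integrated stress response, a program cells switch on when translation initiation is held back, 16 rose. With a library left out these counts were 10 to 16 and 8 to 14, and with an estimated correlation between genes neither list passed the camera test (adjusted p = 0.41 for each). The myelin list did not pass that test either (adjusted p = 0.41). The rotation test fry gave adjusted p of 0.0079 for cholesterol synthesis and 0.0101 for the stress response. Trib3 went from 1.13 ± 0.76 CPM to 34.6 ± 14.2 CPM and Atf5 from 134 ± 25.8 CPM to 1160 ± 162 CPM.

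Of 16569 genes tested with edgeR's quasi-likelihood test, 1255 passed a Benjamini-Hochberg adjusted p of 0.05, with 310 higher and 945 lower in cuprizone. Among them 198 rose and 596 fell by more than 2-fold. The groups did not overlap for 5005 genes (30.2% of those tested, where chance gives 10%). The count of higher genes dropped to 157, 73 and 65 without control replicate 24, 26 or 27 and to 91 without cuprizone replicate 30, and the count of lower genes to 519, 474, 495 and 480 in the same order. DESeq2 called 862 genes higher and 1400 lower. Cuprizone replicate 32 stood apart from its group, with a chi-square per degree of freedom of 85.1 and 101 against replicates 30 and 31, which had 26.6 between them. Without it 464 genes were higher and 963 lower.

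**Figure D1:**
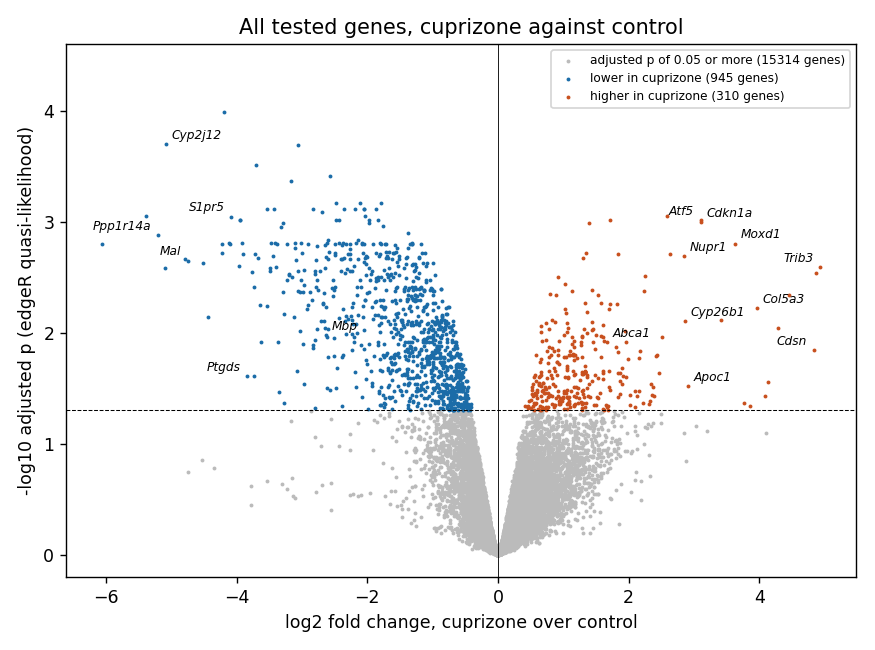
Each point is 1 of the 16569 genes tested; the horizontal axis is the log2 fold change of cuprizone over control and the vertical axis the -log10 of the adjusted p from edgeR, with a dashed line at an adjusted p of 0.05. The 945 genes lower in cuprizone (blue) outnumber the 310 higher ones (orange), and Trib3 at 4.94 and Ppp1r14a at -5.20 lie near the ends of the named changes.

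All 28 genes of the myelin and mature oligodendrocyte list had a negative fold change and 27 passed the test (28 when adjusted over the list alone), with a median log2 fold change of -2.87. The camera test gave the list an adjusted p of 1.1e-29 with a preset correlation between genes (adjusted p = 0.41 with an estimated correlation). The list took 8.22% ± 0.955 of all counts in the control libraries and 1.48% ± 0.545 in the cuprizone libraries (SD, n = 3). The largest falls in it were those of Ppp1r14a, an inhibitor of myosin phosphatase (ENSMUSG00000037166, chromosome 7, 29289308 to 29293801 in GRCm38), at -5.20 ± 0.40, and of Mal, a proteolipid of compact myelin, at -4.74 ± 0.47. Mobp, Anln and Ptgds had log2 fold changes of -3.76, -3.72 and -3.83. The adjusted p of Ptgds reached 0.0714 when control replicate 24, 26 or 27 or cuprizone replicate 32 was left out, and that of Mbp reached 0.0558 without cuprizone replicate 30. Outside the fixed lists, the largest falls were those of Cyp2j12, a cytochrome P450 (-5.08), S1pr5, a sphingosine 1-phosphate receptor (-4.08), Adamtsl4 (-3.95) and Itgb4, an integrin that binds laminin (-3.92).

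Earlier stages of the lineage moved less than the myelin genes. Of 13 newly formed oligodendrocyte genes 1 passed, Enpp6, a phosphodiesterase made as oligodendrocytes begin to differentiate, which fell by 1.18 on the log2 scale (4 fell when adjusted over the list alone). Its adjusted p was up to 0.0758 without control replicate 24, 26 or 27, and the list as a whole had an adjusted p of 0.17 with camera, or 0.0339 without control replicate 27. In addition 2 members fell without cuprizone replicate 31 and 1 rose without cuprizone replicate 32. Tmem163 and Nkx2-2 had log2 fold changes of -0.63 and -0.69 with adjusted p of 0.0592 and 0.0983. None of the 14 progenitor genes passed with edgeR, DESeq2 or limma-voom, and 1 had an unadjusted p under 0.05. The list's median was -0.10 (0.07 without cuprizone replicate 32) and its camera adjusted p 0.42. Olig1, whose promoter drives Cre in these mice, went from 1438 ± 184 CPM to 661 ± 167 CPM (log2 fold change -1.12 ± 0.24, adjusted p = 0.0334), and its adjusted p was up to 0.113 without control replicate 24, 26 or 27 or cuprizone replicate 30. Rpl22, the gene that carries the tag, was at 70.4 ± 7.14 CPM and 76.4 ± 9.97 CPM (adjusted p = 0.66). In the list of genes reported for oligodendrocytes in disease, 3 of 15 rose and 3 fell. Those that rose were Cdkn1a, an inhibitor of the cell cycle (3.11), Anxa2 (1.32) and H2-K1 (0.65), and those that fell were Il33, an alarmin (-2.97), Klk6 (-2.81) and Plin4, a coat protein of lipid droplets (-2.61), so that the median of 0.60 and the camera adjusted p of 0.16 cover changes in both directions. With a single library left out, between 1 and 3 of its members rose and 1 or 2 fell, and the median ran from 0.29 without control replicate 27 to 0.76 without control replicate 24. The adjusted p of Plin4 was up to 0.119 without control replicate 24 or 26 or any cuprizone library, and 0.0738 with limma-voom. Anxa2 was at up to 0.123 without any library but control replicate 24, H2-K1 at up to 0.205 without the same libraries. Klk6 was at up to 0.137 without a control library or cuprizone replicate 31 and up to 0.0814 with upper-quartile scaling, no filter or GC content and length trends removed. When adjusted over the list alone, 6 of its members rose and 3 fell.

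The 20 enzymes of cholesterol biosynthesis all had negative fold changes, and 15 fell (19 when adjusted over the list alone). Their median log2 fold change was -1.15, with a camera adjusted p of 8.5e-16 (adjusted p = 0.41 with an estimated correlation). Fdps, which makes farnesyl diphosphate (ENSMUSG00000059743, chromosome 3, 89093588 to 89101959), went from 30.5 ± 1.29 CPM to 12.3 ± 0.748 CPM, a log2 fold change of -1.31 ± 0.11 (adjusted p = 0.00157). Dhcr7, which catalyses the last step to cholesterol (ENSMUSG00000058454, chromosome 7, 143823145 to 143848410), went from 120 ± 8.91 CPM to 40.1 ± 6.17 CPM, and Ebp, a sterol isomerase, had a log2 fold change of -1.15. The fall was present in each cuprizone library, with mean log2 levels of the list at -1.02, -0.97 and -1.43 relative to the control mean in replicates 30, 31 and 32.

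Genes of cholesterol uptake, transport and regulation went both ways. Of 25, 6 fell and 2 rose (8 and 3 when adjusted over the list alone), the median was -0.02 and the camera adjusted p 0.44. Abca2, a lipid transporter of endosomes and lysosomes, had a log2 fold change of -2.40 and Stard3, a sterol transfer protein of late endosomes, one of -0.87. Abca1, which exports cholesterol to apolipoproteins (ENSMUSG00000015243, chromosome 4, 53030787 to 53159895), rose from 54.8 ± 10.9 CPM to 175 ± 55.8 CPM (1.67 ± 0.27, adjusted p = 0.0121), with an adjusted p of up to 0.0567 without control replicate 24 or 27. The other riser was Soat1, which esterifies cholesterol (0.70), named after its value was seen, with an adjusted p of up to 0.129 when any library but cuprizone replicate 32 was left out. Srebf2, the transcription factor that drives sterol synthesis, and the exporter Abcg1 had log2 fold changes of -0.56 and -0.31 with adjusted p of 0.12 and 0.29. Apoe, the main apolipoprotein of brain, stood at 10337 CPM in control and 18237 CPM in cuprizone (0.82 ± 0.32, adjusted p = 0.18). The median was 0.13 without control replicate 26, and the number of members that fell was 3 without control replicate 26 or 27. The number that rose was 0 without control replicate 24, 1 without control replicate 26 or 27 or cuprizone replicate 30 or 31, and 3 without cuprizone replicate 32.

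Of 20 genes of fatty acid, sphingolipid and galactolipid synthesis, 10 fell and none rose (13 fell when adjusted over the list alone). Fa2h, which hydroxylates the fatty acids of myelin galactolipids, had a log2 fold change of -3.29 ± 0.24, Cers2, which makes very long chain ceramides, one of -2.07 ± 0.17, and Elovl1, which elongates very long chain fatty acids, one of -1.72 ± 0.15. Fa2h and Ugt8a also belong to the myelin list. The camera adjusted p was 3.7e-11 (adjusted p = 0.63 with an estimated correlation).

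**Figure D2:**
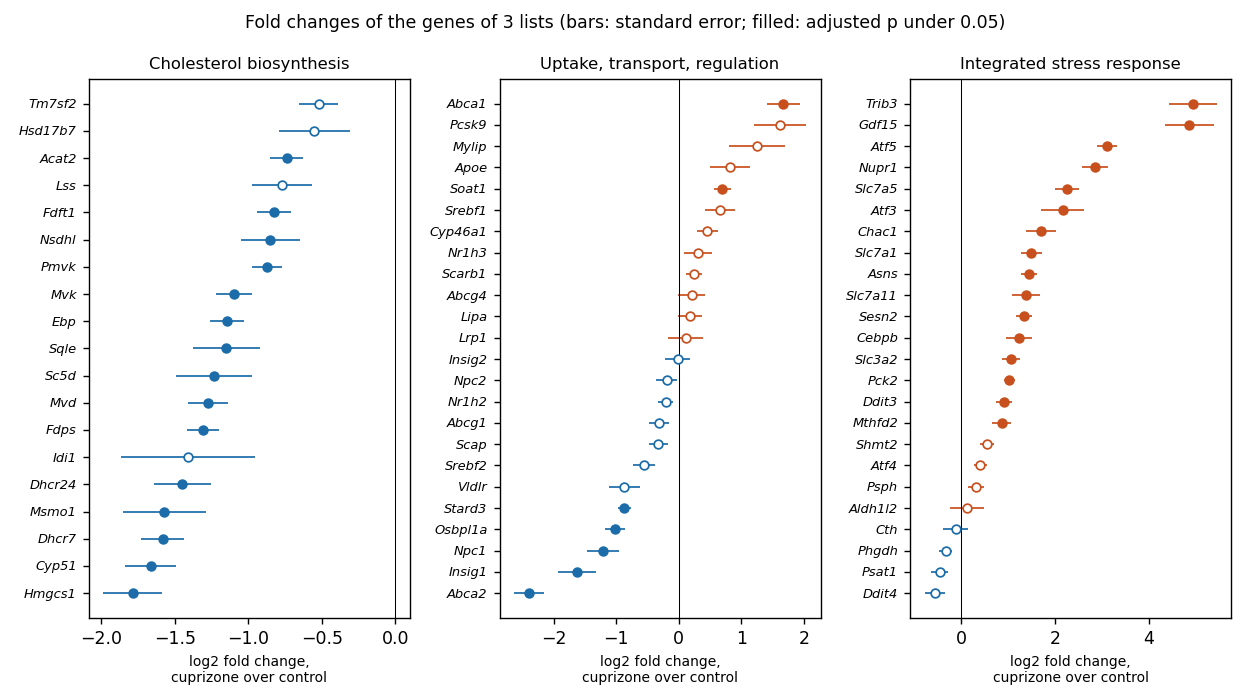
Log2 fold changes of cuprizone over control (horizontal axis) for tested genes of the cholesterol biosynthesis, cholesterol uptake, transport and regulation, and integrated stress response lists; points are edgeR estimates, bars their standard errors, and filled points have an adjusted p under 0.05. The plot leaves out 1 of the 20 biosynthesis genes and 1 of the 25 uptake and transport genes. The biosynthesis genes drawn all lie below 0, those of uptake and transport on both sides, and 16 of 24 stress genes are filled above 0.

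The integrated stress response list rose, with 16 of 24 tested members higher and none lower (18 higher and 1 lower when adjusted over the list alone, the latter Ddit4 at -0.56). The median log2 fold change was 1.14 and the camera adjusted p 4.8e-10 (adjusted p = 0.41 with an estimated correlation). Trib3, a pseudokinase induced by ATF4 (ENSMUSG00000032715, chromosome 2, 152337422 to 152344032), had the largest log2 fold change of the list at 4.94 ± 0.51 (adjusted p = 0.00254). Atf5, a transcription factor whose own translation rises in this response, had 3.11 ± 0.22, and Nupr1, a stress-induced chromatin protein, 2.85 ± 0.27. Atf5 overlaps Il4i1 and Nup62 on the opposite strand, and the strand setting of the counting is not given in the sources used here. Fewer members passed with a control left out, with 10 without control replicate 26 and 8 without control replicate 27, and 10 passed without cuprizone replicate 30. In contrast none of the 17 endoplasmic reticulum chaperone genes passed with edgeR or limma-voom. Of these 1 had an unadjusted p under 0.05, DESeq2 called 1 lower, and the camera adjusted p was 0.95. Hsp90b1, Manf and Herpud1 had log2 fold changes of -0.34, 0.27 and 0.28.

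Of 15 p53 targets 2 rose and 1 fell (5 and 2 when adjusted over the list alone). Cdkn1a, which encodes p21, went from 13.03 ± 2.60 CPM to 112 ± 23.4 CPM (3.11 ± 0.22, adjusted p = 0.00101), Btg2 had a log2 fold change of 1.06, and Phlda3 one of -0.73. The camera adjusted p of 0.0107 became 0.15 when Cdkn1a and Btg2, which other lists also hold, were left out, and 0.63 with an estimated correlation. The adjusted p of Btg2 was up to 0.0945 without control replicate 24, 26 or 27, and that of Phlda3 up to 0.139 without any of these or cuprizone replicate 30, 0.0573 with upper-quartile scaling and 0.0673 after trends on GC content and length were removed. Without cuprizone replicate 32, 6 members rose. Of 14 immediate early genes 3 rose (8 higher and 1 lower when adjusted over the list alone, 6 higher with DESeq2), Atf3 (2.16 ± 0.45), Fos (1.30 ± 0.28) and Btg2, with a camera adjusted p of 2.3e-04 (adjusted p = 0.71 with an estimated correlation). Between 0 and 4 members rose with a single library left out. The adjusted p of Atf3 was up to 0.13 without control replicate 26 or 27 or any cuprizone library. That of Fos was up to 0.12 without control replicate 24 or 27 or cuprizone replicate 30 or 32.

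Among the other large rises were Moxd1, a monooxygenase-like protein, from 12.7 ± 1.99 CPM to 157 ± 55.5 CPM (3.63 ± 0.31), Col5a3, a collagen chain (3.97 ± 0.52), Cyp26b1, which degrades retinoic acid (2.86 ± 0.41), and Cyb5r2 (2.64 ± 0.25). Cdsn, known as an adhesion protein of skin, was at 1.19 ± 0.222 CPM in control and 34.3 ± 34.6 CPM in cuprizone, and its adjusted p of 0.0143 was up to 0.0693 without control replicate 24, 26 or 27 and 0.0760 with limma-voom. Apoc1, an apolipoprotein, had a log2 fold change of 2.91 ± 0.59, with an adjusted p of up to 0.123 without control replicate 26 or 27 or cuprizone replicate 30.

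Markers of other cells were present in every library and shifted unevenly. The astrocyte list had 16 tested members, of which none passed with edgeR, DESeq2 or limma-voom and none had an unadjusted p under 0.05. Gfap, an intermediate filament of astrocytes, was at 5995 CPM in control and 9483 CPM in cuprizone (adjusted p = 0.30), the glutamate transporter Slc1a2 at 9992 CPM and 6798 CPM (adjusted p = 0.40), and Gjb6 had a log2 fold change of 0.49. The list's camera adjusted p of 0.84 became 0.0044, with 2 members higher, without cuprizone replicate 32. In the reactive astrocyte list 3 of 15 rose (12 when adjusted over the list alone, 11 with DESeq2), Tgm1 (2.32 ± 0.53), Hspb1 (1.61 ± 0.32) and S100a10 (0.87 ± 0.20), with a median of 1.45 (1.12 to 1.80 with a library left out) and a camera adjusted p of 2.4e-06 (adjusted p = 0.71 with an estimated correlation). Without control replicate 26 or 27 or cuprizone replicate 30 none of its members passed, 1 passed without cuprizone replicate 31, and 7 passed without cuprizone replicate 32. The adjusted p of Tgm1, Hspb1 and S100a10 was up to 0.138, 0.105 and 0.16 in these fits, and that of Tgm1 was 0.0657 without control replicate 24 and 0.0591 with no filter on low counts.

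None of the 20 microglia and macrophage genes passed with edgeR or limma-voom; 4 had an unadjusted p under 0.05 and DESeq2 called 2 higher. Cd68, Ptprc and Lyz2 had log2 fold changes of 1.52, 1.27 and 1.58 with adjusted p of 0.11, 0.13 and 0.19. The list's camera adjusted p was 0.00214, 0.16 without cuprizone replicate 32 and 0.90 with an estimated correlation. Its mean level relative to the control mean was 0.61, -0.21 and -0.40 in control replicates 24, 26 and 27 and 0.17, 0.55 and 1.40 in cuprizone replicates 30, 31 and 32. Of 20 genes of activated phagocytes 1 rose (2 when adjusted over the list alone), Lgals3bp, a secreted glycoprotein (0.78 ± 0.13), and its adjusted p was up to 0.0695 without control replicate 26 or 27. DESeq2 called 10 of the 20 higher, and 12 had an unadjusted p under 0.05. Gpnmb and Lgals3 had log2 fold changes of 2.49 and 2.10 with adjusted p of 0.0538 and 0.0767, and the camera adjusted p was 1.2e-05 (adjusted p = 0.72 with an estimated correlation). None of the 7 MHC class II genes passed over all genes tested with edgeR or limma-voom, 6 rose when adjusted over the list alone, 6 had an unadjusted p under 0.05 and DESeq2 called 2 higher. The invariant chain gene Cd74 had a log2 fold change of 2.24, H2-Eb1 2.12 and H2-Ab1 2.04, and the camera adjusted p was 0.00175 (adjusted p = 0.71 with an estimated correlation). Of 23 MHC class I and interferon genes 3 rose (5 when adjusted over the list alone and 5 with DESeq2), the peptide transporters Tap1 (0.73) and Tap2 (0.63) and H2-K1 (0.65), with a camera adjusted p of 1.8e-04 (adjusted p = 0.71 with an estimated correlation). None of the 3 was past the threshold without control replicate 26 or 27 or cuprizone replicate 30 or 31, with adjusted p of up to 0.15, 0.132 and 0.205. Without control replicate 24 Tap1 and Tap2 did not pass (0.108 and 0.0864), without cuprizone replicate 32 Tap1 and H2-K1 did not (0.0816 and 0.0634), and with no filter on low counts neither of the latter did (0.0517 for each). Tap1 was also at 0.0512 with RLE scaling and 0.0527 with thinned counts. Only 2 of the 12 lymphocyte markers had enough counts to be tested, and both rose: Cd4 (1.58 ± 0.24), with an adjusted p of 0.0518 without control replicate 26, and Lck (1.21 ± 0.26), with an adjusted p of up to 0.141 when any 1 of the 6 libraries was left out.

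**Figure D3:**
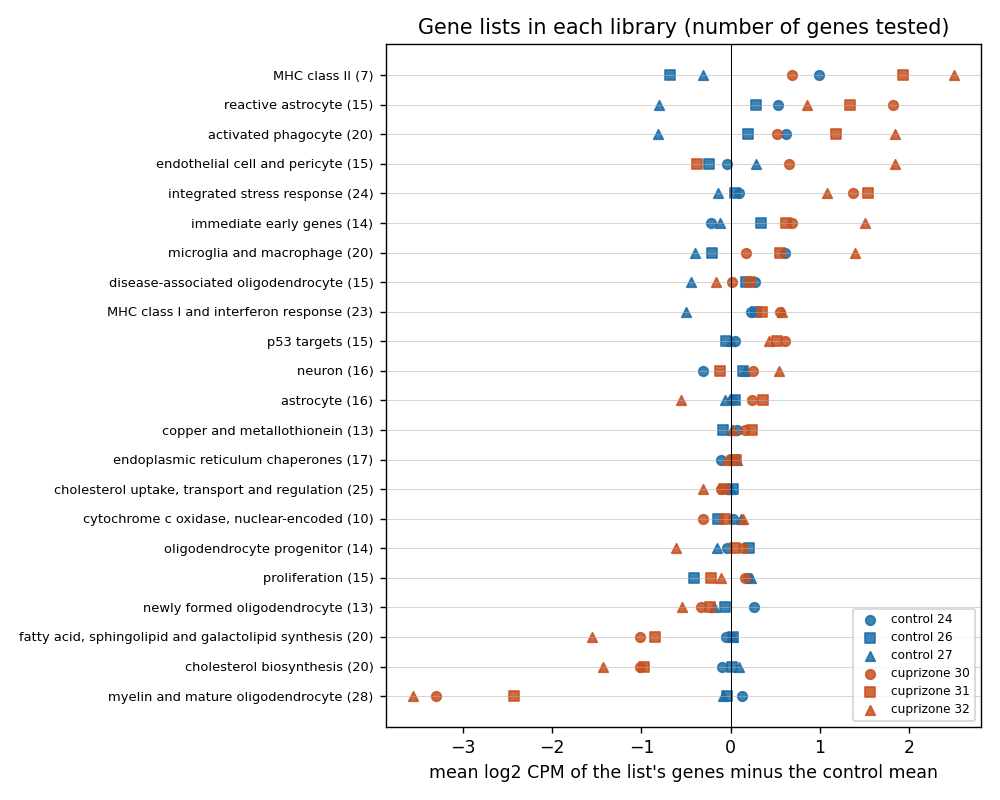
Mean log2 CPM of the gene lists drawn, relative to the mean of the 3 controls (horizontal axis), with 1 point per library. Blue marks control, orange cuprizone, and the shape the replicate. The lists of red blood cells, fibroblasts and meninges, lymphocytes, mitochondrially encoded genes, and ependymal cells and choroid plexus are not drawn. The myelin list lies at -3.30, -2.42 and -3.56 and the integrated stress response list at 1.37, 1.54 and 1.08 in cuprizone replicates 30, 31 and 32. The microglia list lies at 0.17, 0.55 and 1.40 in the same libraries. Only replicate 32 is above the highest control, replicate 24 at 0.61.

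The remaining lists had no member past the threshold with edgeR. For all 14 such lists together, 171 genes were tested, 15 had an unadjusted p under 0.05 in the direction of a rise and 4 in that of a fall, DESeq2 called 6 higher and 2 lower, and limma-voom called 0. With a library left out, calls appeared in 3 of these lists: 2 astrocyte genes and 1 copper gene without cuprizone replicate 32, and 2 endothelial genes without cuprizone replicate 31. The camera adjusted p was 0.42 for neurons (Nefl 0.58, Nefm 0.51 and Tubb3 -0.23 on the log2 scale), 0.83 for ependymal cells and choroid plexus (Folr1 -3.53, Otx2 -2.55 and Clic6 -2.68), 0.85 for fibroblasts and meninges (Igfbp2 -1.06, Mgp 0.85 and Fmod 0.46) and 0.76 for red blood cells (Hba-a2 1.56, Alas2 1.29 and Hba-a1 1.46). Single libraries carry the folds of some of these genes. Control replicate 27 had 50.4 CPM of Folr1, 16.5 of Otx2 and 119 of Clic6, where no other library had more than 2.31, 2.18 and 8.38, and without it the median of the ependymal list went from -0.08 to 0.29. That median also moved to -1.30 without cuprizone replicate 32 and to -0.44 without control replicate 26. Igfbp2 was likewise at 192 CPM in control replicate 27 and at most 55.5 in the others. Hba-a2 was at 0.225, 1.45 and 12.8 CPM in cuprizone replicates 30, 31 and 32, and without replicate 32 the median of the red blood cell list went from 1.41 to -1.28. With any other library left out this median ran from 0.86 (without control replicate 26) to 2.60 (without control replicate 27). For endothelial cells and pericytes the camera adjusted p was 0.0379 (Slc2a1 -0.42, Flt1 1.34 and Pecam1 1.11), 0.90 with an estimated correlation, 0.0838 with upper-quartile scaling, 0.14 with the stricter filter, and 0.0747, 0.10, 0.0791 and 0.53 without control replicate 24 or 26 or cuprizone replicate 30 or 32. For proliferation it was 0.82 (Pcna -0.33, Ccnb2 0.63 and Birc5 -0.56), or 0.035 without control replicate 26 (median -0.27, against -0.12 with all libraries and 0.04 without control replicate 24 or 27). Genes of copper handling and metallothioneins (Cp 1.62, Atp7b 0.67 and Sco1 -0.20) had 0.76, nuclear-encoded subunits of the copper enzyme cytochrome c oxidase (Cox6c -0.20, Cox7a2 -0.16 and Cox7b -0.10) 0.67, and mitochondrially encoded genes (mt-Nd1 -0.36, mt-Co1 -0.24 and mt-Nd2 -0.27) 0.72.

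The number of animals behind each library is not given in the sources used here, so the p-values measure the spread between these 6 samples. No library of RNA before the pull-down was used here, so levels of other cells' markers are those of the captured RNA. Enrichment for the oligodendrocyte lineage was therefore not measured, and a change in captured RNA need not lie in that lineage.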

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

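The removal of GC content and length trends was chosen after the data were seen; the other alternatives were fixed before. DESeq2 called 862 genes higher where edgeR called 310, and the cause was not tested. Over the other alternatives that kept all 6 libraries, 285 to 356 genes were higher and 857 to 996 lower. With a library left out the counts ran from 65 to 464 higher and from 474 to 963 lower, with fewer samples in the fit. With an estimated correlation the camera adjusted p was 0.41 for cholesterol biosynthesis and 0.41 for the myelin list, whose estimated correlations between genes were 0.38 and 0.74; both passed in every other run of the list tests, with fry at 0.0079 for each. No list test was run with DESeq2, limma-voom or the fit without robust estimation. The uptake, transport and regulation list passed in none of the runs, with adjusted p from 0.17 to 0.90. These list tests look for a shift in 1 direction, so they can miss a list with 6 members lower and 2 higher of 25. Of 101 genes chosen for naming, some of them left out of the text, 50 passed, 29 of these under every alternative run; the other 21 each lost the call when at least 1 library was left out, and no call changed direction. The upper-quartile factors shifted log2 fold changes by a median of 0.06, the largest shift of the 3 scalings. At this depth and with 3 libraries per group, 28% of simulated falls and 64% of simulated rises of 1 on the log2 scale were recovered. This was a single draw with 50 genes at each size, and far fewer genes changed in it than were called in the data. These shares therefore do not give the power in the data or a difference in power between falls and rises.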

Other observations

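The tests below that compare the cholesterol list with the myelin list and the stress list with the astrocyte list were chosen after those medians had been seen, as was the use of the activated phagocyte, MHC class II and reactive astrocyte lists; the others were set before their results. Further genes were listed by group after the results had been seen, and no set test was made of these groups. In the apolipoprotein cluster beside Apoe, Apoc2 and Apoc4 had log2 fold changes of 4.09 ± 0.89 and 4.13 ± 0.82 (SE, edgeR adjusted p = 0.037 and 0.0276), from control levels of 0.173 and 0.234 CPM that rest on few counts. Apoc2 was at an adjusted p of up to 0.14 without control replicate 24, 26 or 27 or cuprizone replicate 31, and Apoc4 at up to 0.111 without control replicate 26 or 27, while limma-voom gave Apoc2 0.098. Of 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs and include targets of ATF4, 16 had a positive fold change and 4 passed, Eprs (0.87), Lars (0.78), Nars (0.53) and Cars (0.48), and the median was 0.29. Without control replicate 27 the adjusted p of these 4 was 0.118, 0.0543, 0.155 and 0.184. Eprs also missed the threshold without control replicate 26 or cuprizone replicate 30 (0.103 and 0.0756), Nars without every library but cuprizone replicate 32 (0.0657 to 0.155), and Cars without any of the 6 (0.0566 to 0.184) and with no filter on low counts (0.0548). Of 5 transcription factors of the oligodendrocyte lineage 3 fell, Sox10 (-1.25), Olig1 (-1.12) and Sox8 (-1.10), while Olig2 (-0.46) and Zfp488 (-0.04) did not pass. The adjusted p of Sox10 was up to 0.116 without a control library or cuprizone replicate 30, that of Sox8 up to 0.0622 without control replicate 26 or cuprizone replicate 30, and that of Olig2 was 0.0288 without cuprizone replicate 31.

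Lower cholesterol biosynthesis transcripts were not accounted for by GC content and gene length, since the median stayed at -1.15 (95% interval -1.36 to -0.84) after trends on both were removed. A smaller share of mature oligodendrocytes in the captured RNA stays open as an account of the fall. The cholesterol median lay 1.72 above the myelin median (1.34 to 2.39), within what the loss of these cells allows. Both medians were known when this comparison was set, and any list that fell less than the myelin list would meet it. It therefore adds no evidence for that account. Sterol excess, which lowers synthesis and raises targets of liver X receptors, also stays open. The median of 5 such targets was 0.68, above the 0.3 set before their single values had been looked at, and 3 had a positive fold change. Over 5 genes the bootstrap interval of -0.11 to 1.25 is the range of the single values. That it includes 0 shows only that not every target rose, so it does not measure the uncertainty of the median. Mylip, 1 of the 5, belongs to the uptake list, whose summary had been seen, and the median of the other 4 was 0.302 (range -0.11 to 0.73). None of the 5 passed. Of other targets in the fixed naming set, Abca1 rose by 1.67 (adjusted p = 0.0121, up to 0.0567 without control replicate 24 or 27), while Apoe (0.82) and Abcg1 (-0.31) did not pass. Apoc1, Apoc2 and Apoc4, in the cluster beside Apoe, rose by 2.91, 4.09 and 4.13 but were not part of this test. Each lost the call without control replicate 26 or 27. An effect of cuprizone on sterol synthesis within surviving cells was not separated from these.

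The median of integrated stress response genes, 1.14, lay above the 0.02 of all tested genes. The rise was thus more than one shared by all transcripts as myelin ones leave the libraries. The stress median exceeded the astrocyte median by 1.07 (0.47 to 1.50), a comparison set with both medians known. Lists of other cells differed, with medians of 0.24 for neurons, 1.19 for endothelial cells and pericytes and 1.26 for activated phagocytes. The astrocyte comparison therefore cannot exclude a relative rise of RNA from some other cells. The stress rise did not rest on cuprizone replicate 32, without which the median was 1.13 (0.65 to 1.68). Added RNA of microglia and macrophages was tested without replicate 32, which had the most of these markers. The microglia median then lay below the stress median, with a difference of -0.81 (-1.43 to -0.33). With all 6 libraries the difference was -0.40 (-0.83 to 0.21), and without control replicate 24 it was -0.01 (-0.48 to 0.57). The result thus depended on the libraries used. Stress genes raised within microglia already captured need no rise of markers, so the comparison cannot exclude these cells as a source. Activated phagocytes or cells rich in MHC class II stay open, since without replicate 32 the differences of their lists from the stress list were -0.52 (-1.12 to 0.14) and 0.44 (-0.82 to 0.93). With all 6 libraries these differences were 0.11 (-0.60 to 0.73) and 0.89 (-0.25 to 1.45). Without control replicate 24 they were 0.55 (-0.35 to 1.14) and 1.68 (0.11 to 2.20). The medians of the reactive astrocyte and stress lists were 1.45 and 1.14. Of 15 reactive astrocyte genes 3 passed, and 0 without control replicate 26 or 27 or cuprizone replicate 30, and the list passed neither camera with an estimated correlation (0.71) nor fry (0.186). The stress list had 0.41 and 0.0101 in these 2 tests. Stress in astrocytes was not separated from stress in the oligodendrocyte lineage. A response to cuprizone in cells whose RNA was captured, of any of these kinds, is a candidate explanation, as a hypothesis found and tested on the same data.

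Genes known from striatal projection neurons were among those that rose, with 13 noticed among the calls, such as Gpr6 (1.72) and Drd2 (1.31, with an adjusted p of up to 0.0868 without control replicate 24 or 26 or cuprizone replicate 30). Of the 13, 10 lost the call without control replicate 24 and as many without control replicate 26, 8 without control replicate 27 or cuprizone replicate 30, and 2 with limma-voom, and 3, Gpr6 among them, kept it in every setting. The rise did not come from a single library, since 3 of the 3 cuprizone libraries had a mean of 12 further striatal markers above every control. The median of 12 cortical markers lay lower, with a difference of -0.63 (-1.06 to -0.37). Of these cortical markers 11 had a positive fold change and 0 passed, with a median of 0.27 (0.14 to 0.44). An equal rise of all neurons would not give that difference, but a smaller general rise as part of it is not excluded. Striatal tissue in the cuprizone dissections may be the source: the 12 further markers, picked as not past the threshold and all counted in control libraries too, had a median of 0.90 (0.77 to 1.33), with 0.99 for Ppp1r1b and 0.23 for Adcy5, the most abundant of them at 408 and 256 CPM in control. The striatum lies below the corpus callosum and the labels name only the latter. The pull-down is meant to remove RNA of untagged cells, but markers of other cells were present in every library. How far it removed them was not measured, and a change in neurons themselves was not tested.

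Other splits of the 6 samples into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 1255 genes past the threshold and the highest of the others 0; 1 of the 10 splits gave as many. For cholesterol biosynthesis the real split had the smallest camera p (6.5e-17, unadjusted, against 7.8e-07 for the next), as it had for the myelin list (4.1e-31 against 1.5e-10), so 1 of 10 each. For cholesterol uptake, transport and regulation 4 of the 10 splits had a p as small as the real 0.29, the smallest other being 0.19.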
